A study of Homo sapiens with 8 samples.

How the data were processed

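Total RNA from human umbilical vein endothelial cells was profiled by mRNA sequencing in 8 libraries, 2 for each of 4 groups. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a Lexogen mRNA-Seq kit. Groups and replicate numbers were taken from the sample labels. Nothing in the labels says whether the 2 replicates of a group were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

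The deposited values were FPKM, which are fragments scaled by transcript length and by the mapped fragments of the library, 1 value per locus and library, with the locus position on the human genome build hg19. Per the submitters' processing notes, the tools were TopHat2 2.0.9 and Cufflinks, and the build was hg19; the settings of these tools, the annotation and the use of strand were not given in the sources used here. FPKM divides by transcript length and by the library's mapped fragments, so it shows shares of the transcript pool and not absolute amounts. Cufflinks assigns fragments to overlapping or related transcripts by a statistical estimate, so values of loci that overlap or have near-identical copies are uncertain. An estimate can also fail at a locus and be listed at 0. Positions are given as in the files, counted from 1. No hg19 gene annotation was used here, so exons, introns and untranslated regions are not given.

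The files held 31450 loci, of which 7035 had no gene symbol. Another 124 loci, on the Y chromosome or listed as XIST or TSIX, were left out of all analyses, and other loci of the X chromosome were kept. The remaining 24291 named loci were used as deposited, without further scaling. A locus was tested if it reached 1 FPKM in at least 2 of the 8 libraries, which left 11823 loci. Of these, 805 carried a symbol found on several loci, 527 were listed under several genes and 20 lay on haplotype or unplaced sequences.

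Values were analysed as log2(FPKM + 1), so a log2 change understates the change of a gene with a low FPKM. A linear model with a mean for each of the 4 groups was fitted to all 8 libraries with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a mean-variance trend), and the groups thus shared 1 estimate of the spread. The residual degrees of freedom were 4 and the prior degrees of freedom 4.28. The median residual SD was 0.133 on the log2 scale. All tests were two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all loci tested. There were 8 contrasts: the 6 differences between pairs of groups, the mean of COMP-Ang1 and ABTAA minus the mean of control and ABA (the Tie2-activating arms against the other arms), and the interaction, which is ABTAA minus ABA less COMP-Ang1 minus control. A moderated F test asked for any difference among the 4 groups.

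The groups, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. For each contrast the rule took up to 10 called genes with the largest rise and up to 10 with the largest fall, with a mean of at least 2 FPKM in a group and no overlap between the samples compared. It added up to 4 called members of each list, and 10 genes whatever their values: ANGPT2, TEK, TIE1, FOXO1, ESM1, KLF2, CCND2, VCAM1, ICAM1 and PECAM1. The rule left out symbols on several loci and small RNA genes, but the choice of list members did not apply this to symbols on several loci, a departure through which PDGFB is printed. Genes printed from outside the rule were chosen after their values were seen: SNORA10, the list members CITED2, GABARAPL1, JUN, DUSP4, TGFB2, CYR61, CDH2, F2R and PROCR in the activating arms, the markers KRT8, KRT18, KRT19, RGS5, CD68, NRP2 and HBA1, and in the closing section CRIM1, RBMS3, ANKRD1 and ALDH1A1.

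Gene lists were tested with limma's camera on the same model, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 20 lists of a contrast. The lists were FOXO target genes, Tie2 pathway components, endothelial identity, inflammation and leukocyte adhesion, flow-responsive and vasoprotective genes, Notch pathway, tip-cell genes, endothelial junctions, cholesterol synthesis, glycolysis and hypoxia response, MYC and ribosome biogenesis, cell cycle, immediate early and ERK feedback genes, ATF4 and amino acid response, type I interferon response, TGF-beta and BMP response, basement membrane and matrix, coagulation and fibrinolysis, apoptosis and survival, and heat shock and unfolded protein response. Another 5 lists held markers of other cell types: smooth muscle, pericyte and fibroblast markers, leukocyte markers, erythroid and platelet markers, lymphatic endothelial markers, and epithelial and keratinocyte markers. Lists of YAP and TEAD targets, arterial genes and venous genes were made after the results were seen. Each camera result was repeated with the correlation estimated from the data, and with fry, which asks whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes.

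FPKM files hold no fragment totals. Relative depth was the inverse of the commonest FPKM ratio to control replicate 1, over loci above 0 and under 0.3 FPKM in both libraries. This gave 0.934 and 1.02 for the COMP-Ang1 libraries and 0.992 and 0.903 for ABA, each relative to control replicate 1. It gave 1.09 and 0.999 for ABTAA and 0.961 for control replicate 2. The absolute depth is unknown, so no counting interval or detection floor is given.

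The procedure was tested on simulated data with the real means and spreads and 200 changed genes among 11823. Noise was drawn independently for each gene. The changed genes were drawn only from loci above a minimum mean level, so the rates do not hold for lowly expressed loci. For COMP-Ang1 against control it recovered 39.2% of log2 changes of 0.5, 97.0% of changes of 1 and 99.9% of changes of 2, and 5.64% of the calls were false. For the activating arms against the other arms it recovered 83.7%, 99.6% and 99.7%, with 5.49% false calls. In COMP-Ang1 against control, every simulated list of 25 genes shifted by 0.3 had an unadjusted camera p under 0.05. With independent noise, this does not show how camera performs on lists of correlated genes.

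The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, the replicate number as a block, robust eBayes, only the groups compared in the fit, a 2-group fit of the averaged arms, and each library left out in turn. Leaving out a library leaves 1 sample in its group, and the fit then assumes that this lone sample varies like the other groups. Removing NOTCH1 and EIF2C2, the loci listed at 0 in both libraries of 1 group and at 10 FPKM or more in the 6 others, was added after the data were seen. Comparisons that share the control libraries were set beside 100 simulations of unchanged groups against the same controls.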

Results

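Human umbilical vein endothelial cells (HUVEC), primary cells from the lining of the umbilical vein, were sequenced at passage 5 after 6 h of starvation and 4 h of treatment. The series examined how activation of Tie2, the endothelial receptor tyrosine kinase encoded by TEK, changes transcripts. There were 4 groups of 2 libraries. Controls received no reagent. COMP-Ang1, an engineered form of the Tie2 ligand angiopoietin-1, was given at 0.2 µg/ml. The other 2 groups received angiopoietin-2 (Ang2), a context-dependent Tie2 ligand, at 2 µg/ml together with an antibody: ABA, which blocks Ang2, or ABTAA, which binds Ang2 and activates Tie2. A group with Ang2 alone was not analysed here, so ABA and ABTAA each differ from control by an antibody and by Ang2. The series text speaks of 3 antibodies, although COMP-Ang1 is a ligand.

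The libraries had similar relative depths, between 0.903 and 1.09 of control replicate 1, and absolute depth was unknown. Between 11353 and 11443 named loci reached 1 FPKM in a library. The 10 most abundant loci held between 24.8% and 46.1% of the summed FPKM. Across genes, log2(FPKM + 1) correlated with r between 0.979 and 0.984 for libraries of the same group and between 0.976 and 0.987 for libraries of different groups. The first principal component held 22.8% of the variance and the second 19.3%, and they did not separate the 4 groups. Endothelial genes were abundant, with PECAM1, an endothelial adhesion molecule, at 160 ± 4.08 FPKM (SD, n = 2) in control and TIE1, the co-receptor of Tie2, at 148 ± 13.0.

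The first comparison asked what the Tie2 ligand alone does. After COMP-Ang1, ESM1, which encodes the secreted endothelial proteoglycan endocan, fell from 35.8 ± 1.92 to 11.7 ± 0.341 FPKM (SD, n = 2), a log2 change of -1.53 (limma adjusted p = 0.00421). CXCL1, a neutrophil chemokine, fell from 46.1 ± 5.03 to 15.9 ± 2.24 FPKM (log2 change -1.48, adjusted p = 0.00421). CTGF, a matricellular protein, fell from 1081 ± 65.2 to 484 ± 60.7 FPKM (log2 change -1.16, adjusted p = 0.00796). MCTP1, a calcium-binding membrane protein, fell from 69.0 ± 1.53 to 29.1 ± 2.13 FPKM (log2 change -1.22, adjusted p = 0.00163). Rises were seen for GJA4, the gap junction protein connexin 37, from 26.3 ± 4.37 to 59.7 ± 8.69 FPKM (log2 change 1.16, adjusted p = 0.0309), and for PLVAP, a protein of endothelial diaphragms, from 32.1 ± 4.55 to 63.2 ± 2.46 FPKM (log2 change 0.96, adjusted p = 0.0124).

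Among other named genes, GADD45B, a stress-inducible gene, DACH1, a transcriptional cofactor, FBXO32, a ubiquitin ligase subunit, and TNFSF18, a cytokine of the TNF family, fell after COMP-Ang1 with log2 changes of -1.17, -1.11, -1.09 and -1.09. EPHB1, a receptor for ephrins, SLCO2A1, a prostaglandin transporter, and LIPG, endothelial lipase, rose with log2 changes of 1.29, 1.35 and 0.78. The calls of FBXO32, TNFSF18 and LIPG held in only 8, 4 and 8 of 18 alternatives. The locus listed as C10orf54 also rose (log2 change 1.42, adjusted p = 0.0444), but it spans 73156691 to 73575704 on chromosome 10 (hg19), which also holds CDH23, so its reads may come from either gene, and the call held in 7 of 18 alternatives. ANGPT2, which encodes Ang2, had 11.6 ± 0.802 FPKM in control and 6.92 ± 1.13 after COMP-Ang1 (n = 2), and missed the threshold (limma adjusted p = 0.0941). Without a gene annotation, reads of another gene within the locus listed as ANGPT2 could not be told apart, here and below. ICAM1, a leukocyte adhesion molecule, missed it as well (log2 change -0.66, adjusted p = 0.078). In all, 29 of 11823 genes were called by limma, 6 higher and 23 lower, and 1181 had an unadjusted p under 0.05 where 591 were expected by chance. NOTCH1 and EIF2C2 are among the lower ones and were listed at 0 in both COMP-Ang1 libraries. Without control replicate 2 the count was 3, without control replicate 1 it was 15, and without COMP-Ang1 replicate 1 or 2 it was 10 or 16. Without ABA replicate 1 or 2 it was 18 or 17, and without either ABTAA library it was 19.

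Of the 37 FOXO target genes tested, 4 fell after COMP-Ang1 (ESM1, PDGFB, FBXO32 and GADD45B), 0 rose and 33 did not pass, and 7 fell when adjusted over the list alone. The symbol PDGFB, here and below, is found on more than 1 locus, so its values are uncertain. By camera the list was lower (adjusted p = 0.00125), with adjusted p = 0.213 with an estimated correlation. Of 19 inflammation and leukocyte adhesion genes 1 fell, CXCL1, 18 did not pass and 5 fell when adjusted over the list alone (camera adjusted p = 0.000551, and adjusted p = 0.213 with an estimated correlation). Of 22 immediate early and ERK feedback genes, HBEGF, a ligand of the EGF receptor, and ATF3, a stress-induced transcription factor, fell, and 6 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.000551, and adjusted p = 0.432 with an estimated correlation). The call of ATF3 held in only 4 of 17 alternatives. Of 27 TGF-beta and BMP response genes, 2 fell, CTGF among them, and 10 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.00249, and adjusted p = 0.213 with an estimated correlation). Camera also placed MYC and ribosome biogenesis higher (adjusted p = 0.00249, and adjusted p = 0.213 with an estimated correlation), with no member called, and endothelial identity higher and tip-cell genes lower (adjusted p = 0.0172 for both, and adjusted p = 0.544 for both with an estimated correlation). The 3 epithelial and keratinocyte markers tested, KRT8, KRT18 and KRT19, all had positive changes, with a median log2 change of 0.40 against 0.08 for endothelial identity, and 1 rose when adjusted over the list alone. Only these 3 of the 10 markers in that list passed the expression filter. A change of cell type is therefore not shown by them, here and below. The Notch list had a median log2 change of 0.04 and a mean of -0.18, since NOTCH1 was listed at 0.

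ABTAA with Ang2 was compared with control to ask whether the activating antibody changes transcripts as a ligand does. GJA4 rose to 74.9 ± 10.4 FPKM (SD, n = 2) with a log2 change of 1.48 (limma adjusted p = 0.0098), PLVAP rose to 85.0 ± 2.96 FPKM (log2 change 1.39, adjusted p = 0.0075) and LIPG rose from 13.9 ± 1.23 to 33.0 ± 0.79 FPKM (log2 change 1.19, adjusted p = 0.00756). SLCO2A1 rose from 0.912 ± 0.279 to 4.96 ± 0.641 FPKM (log2 change 1.64, adjusted p = 0.00759) and EPHB1 from 0.94 ± 0.125 to 3.96 ± 0.018 FPKM (log2 change 1.36, adjusted p = 0.00756). ESM1 fell to 14.2 ± 2.49 FPKM (log2 change -1.28, adjusted p = 0.0089), and HBEGF fell from 32.7 ± 0.686 to 15.0 ± 1.26 FPKM (log2 change -1.07, adjusted p = 0.00756). MCTP1, CXCL1, CTGF and GADD45B fell with log2 changes of -1.06, -1.05, -1.03 and -1.08. DACH1, SAMD4A, an RNA-binding translational repressor, and HTR1B, a serotonin receptor, fell with log2 changes of -0.93, -0.81 and -0.72, and the call of DACH1 held in 8 of 18 alternatives.

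ABTAA against control gave 19 called genes by limma, 5 higher and 14 lower, with 988 at an unadjusted p under 0.05. Of the lists, endothelial identity was higher by camera (adjusted p = 0.00448, and adjusted p = 0.496 with an estimated correlation), with PLVAP the 1 member of 29 that rose and 4 that rose when adjusted over the list alone. All 3 epithelial and keratinocyte markers tested had positive changes, with a median log2 change of 0.25 against 0.08 for endothelial identity, and 1 rose when adjusted over the list alone. Of 37 FOXO target genes 3 fell, ESM1, PDGFB and GADD45B, and 7 fell and 1 rose when adjusted over the list alone; the median log2 change was 0.02 and the mean -0.13, and camera did not call the list (adjusted p = 0.131). Camera placed inflammation and immediate early genes lower (adjusted p = 0.00159 for both), TGF-beta and BMP response lower and cell cycle higher (adjusted p = 0.0334 for both), each with adjusted p = 0.496 with an estimated correlation. CXCL1, HBEGF and CTGF were the members called in the first 3, and none was called in the cell cycle list. The count of genes was 1 without control replicate 1, 8 without control replicate 2, 2 without ABTAA replicate 1 and 8 without ABTAA replicate 2. It was 0 by limma when only these 4 libraries were fitted.

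ABTAA and ABA were given with the same dose of Ang2, so this comparison separates the antibodies. MCTP1 had 93.1 ± 1.30 FPKM with ABA and 32.6 ± 0.581 with ABTAA (SD, n = 2), a log2 change of -1.49 (limma adjusted p = 0.000498). ESM1 was lower with ABTAA, at 14.2 ± 2.49 against 36.0 ± 3.57 FPKM (log2 change -1.29, adjusted p = 0.00973), as was CXCL1, at 21.8 ± 2.16 against 50.6 ± 1.43 FPKM (log2 change -1.18, adjusted p = 0.011). The locus listed as ANGPT2 was lower, at 7.19 ± 0.562 against 14.1 ± 0.976 FPKM (log2 change -0.88, limma adjusted p = 0.0375). ICAM1 was lower, at 6.45 ± 0.715 against 12.3 ± 0.734 FPKM (log2 change -0.84, adjusted p = 0.0338), a call that held in only 7 of 18 alternatives. GJA4 was higher, at 74.9 ± 10.4 against 25.7 ± 1.48 FPKM (adjusted p = 0.00973).

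Other genes higher with ABTAA than with ABA included SLCO2A1, LIPG, PLVAP and EPHB1, with log2 changes of 1.54, 1.11, 0.98 and 0.86. They also included CYP1A1, a target of the aryl hydrocarbon receptor (1.18), APCDD1, a Wnt inhibitor (1.10), AQP3, a water and glycerol channel (1.00), and LDB2, a LIM-domain binding protein (0.85). SAMD4A, HBEGF, CTGF and SEMA6D, a semaphorin, were lower, with log2 changes of -0.98, -0.93, -0.98 and -0.86. The calls of EPHB1 and SEMA6D held in only 6 and 7 of 17 alternatives. There were 46 called genes, 15 higher and 31 lower, with 1326 at an unadjusted p under 0.05. Endothelial identity was higher by camera (adjusted p = 4.72e-05, and adjusted p = 0.396 with an estimated correlation), with 1 of 29 members that rose and 6 that rose when adjusted over the list alone. Inflammation and leukocyte adhesion was lower (adjusted p = 0.00318, and adjusted p = 0.396 with an estimated correlation), with ICAM1 and CXCL1 lower among 19. Camera also placed FOXO targets (adjusted p = 0.0414), immediate early genes (0.00751) and TGF-beta and BMP response (0.0241) lower and Notch pathway (0.0115) and flow-responsive genes (0.0241) higher, with adjusted p between 0.396 and 0.488 with an estimated correlation. Of the 3 epithelial and keratinocyte markers tested, KRT8, KRT18 and KRT19, 2 rose when adjusted over the list alone. The count of genes was 3 without ABA replicate 2, 8 without ABA replicate 1, 6 and 15 without ABTAA replicates 1 and 2, 27 without either control library and 28 without either COMP-Ang1 library.

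**Figure D1:**
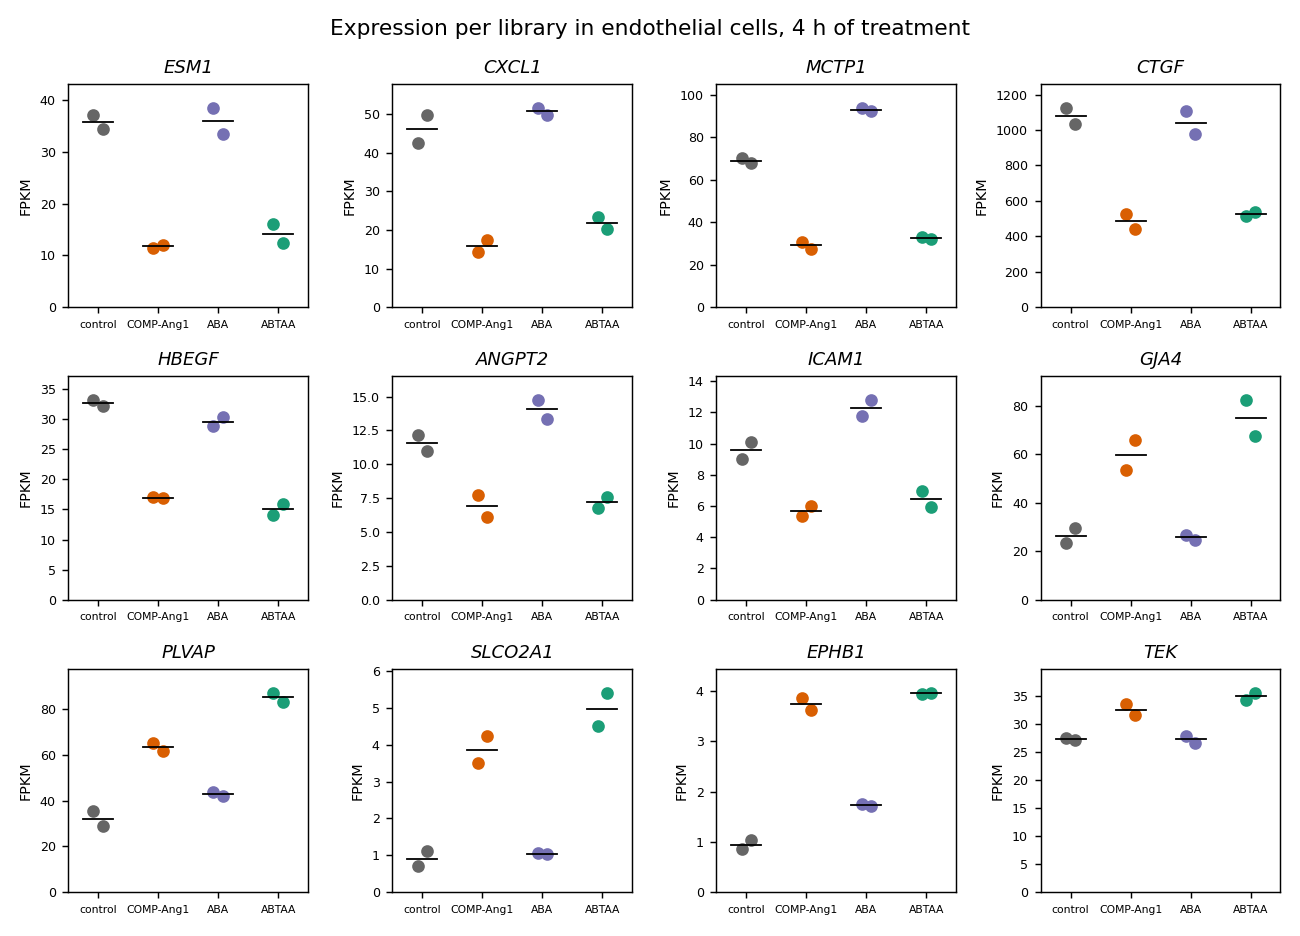
FPKM per library for 12 genes in the 4 groups of endothelial cells, with points for the 2 libraries of a group and a line at their mean, on a linear axis from 0. ESM1 lies near 36 FPKM in control and ABA and at 11.7 and 14.2 in COMP-Ang1 and ABTAA, while GJA4 lies at 26.3 and 25.7 in control and ABA and at 59.7 and 74.9 in COMP-Ang1 and ABTAA.

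Averaging over both activating reagents, with 4 libraries on each side, gave the comparison with the least error. In the Tie2-activating arms, MCTP1 fell with a log2 change of -1.35 (limma adjusted p = 4.27e-05), ESM1 with -1.41 (adjusted p = 0.000414), CXCL1 with -1.33 (adjusted p = 0.000486) and CTGF with -1.07 (adjusted p = 0.000816). The locus listed as ANGPT2 fell by 0.78 on the log2 scale (limma adjusted p = 0.00503) and ICAM1 by 0.75 (adjusted p = 0.00464). SLCO2A1 rose by 1.45 (adjusted p = 0.000816), GJA4 by 1.33 (adjusted p = 0.000825), PLVAP by 0.97 (adjusted p = 0.000816) and LIPG by 0.94 (adjusted p = 0.000825). GJA5, the gap junction protein connexin 40, rose to 3.67 ± 0.698 FPKM with COMP-Ang1 and 4.77 ± 0.0812 with ABTAA (SD, n = 2), from 1.75 ± 0.357 with ABA and a similar level in control, a log2 change of 0.99 (limma adjusted p = 0.00727).

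TEK itself rose slightly, from 27.2 ± 0.26 and 27.2 ± 0.797 FPKM in control and ABA to 32.5 ± 1.39 and 34.9 ± 0.912 in COMP-Ang1 and ABTAA (SD, n = 2), a log2 change of 0.30 (limma adjusted p = 0.0445), and this call held in 8 of 17 alternatives. FOXO1, a transcription factor inhibited downstream of Tie2, missed the threshold (log2 change -0.21, adjusted p = 0.105). TIE1, KLF2, a flow-induced transcription factor, CCND2, a cyclin, and PECAM1 were not called, with log2 changes of 0.06, 0.01, -0.02 and 0.15, and VCAM1 lay below the expression filter. The activating arms gave 274 called genes, 97 higher and 177 lower, with 1928 at an unadjusted p under 0.05. The positions on hg19 were chromosome 5, 54273695 to 54281676 for ESM1, chromosome 4, 74735109 to 74737019 for CXCL1, chromosome 6, 132269317 to 132272518 for CTGF, chromosome 5, 94039416 to 94620279 for MCTP1, chromosome 8, 6261077 to 6501517 for ANGPT2, chromosome 1, 35258599 to 35261348 for GJA4 and chromosome 19, 17462264 to 17488151 for PLVAP. These are spans of the loci as listed, which can be wider than the named gene. The values listed for ANGPT2 may thus include reads of another gene in its span. The count was 88 and 92 without ABA replicates 2 and 1, 100 and 141 without ABTAA replicates 1 and 2, 110 and 180 without COMP-Ang1 replicates 2 and 1, and 112 and 145 without control replicates 1 and 2.

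Of 37 FOXO target genes, 7 fell in the activating arms (ESM1, FBXO32, GADD45B, PDGFB, ANGPT2, CITED2 and GABARAPL1), 0 rose and 30 did not pass. When adjusted over the list alone 9 fell and 3 rose, and camera placed the list lower (adjusted p = 0.007, and adjusted p = 0.409 with an estimated correlation). CITED2, a transcriptional co-regulator, went from 100.4 ± 10.4 FPKM in control and 94.5 ± 3.85 with ABA to 58.9 ± 0.419 and 58.7 ± 14.3 with COMP-Ang1 and ABTAA (SD, n = 2). Without ABTAA replicate 1 the adjusted p of the FOXO list was 0.057. Of 29 endothelial identity genes, 5 rose (PLVAP, MMRN2, FLT1, NOS3 and TEK), 0 fell and 24 did not pass, the calls of FLT1 and NOS3 each held in 7 of 17 alternatives, and 6 rose when adjusted over the list alone (camera adjusted p = 0.000413, and adjusted p = 0.431 with an estimated correlation). MMRN2, an endothelial matrix protein, rose with a log2 change of 0.46, and NOS3, endothelial nitric oxide synthase, with 0.40. KRT19, a marker of epithelial cells, also rose with a log2 change of 0.43 (limma adjusted p = 0.0432).

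Of 19 inflammation and leukocyte adhesion genes, CXCL1, ICAM1 and CCL2, a monocyte chemokine, fell, 0 rose and 16 did not pass, and 9 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.000413, and adjusted p = 0.409 with an estimated correlation). Of 22 immediate early and ERK feedback genes, 5 fell (HBEGF, EGR1, ATF3, DUSP1 and JUN) and DUSP4, a phosphatase that limits ERK signalling, rose, with 9 that fell and 1 that rose when adjusted over the list alone (camera adjusted p = 0.000413, and adjusted p = 0.457 with an estimated correlation). Of 27 TGF-beta and BMP response genes, 5 fell, among them CTGF, ID2, TGFB2 and CYR61, and HEY1, a Notch target, rose, with 11 that fell and 3 that rose when adjusted over the list alone (camera adjusted p = 0.00643, and adjusted p = 0.409 with an estimated correlation). Without COMP-Ang1 replicate 1 the adjusted p of this list was 0.0556.

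Camera did not call the other 15 lists in the activating arms. Of 18 coagulation and fibrinolysis genes, 5 fell, among them THBD, F2RL1, PLAU and F2R, and PROCR, a protein C receptor, rose; the median log2 change was 0.05 and the mean -0.01 (camera adjusted p = 0.907). Of 17 Notch pathway genes GJA4, GJA5 and HEY1 rose, and CXCR4 and NOTCH1 were called lower (adjusted p = 0.322, and adjusted p = 0.763 with an estimated correlation; with NOTCH1 left out adjusted p = 0.0287, and adjusted p = 0.473 with an estimated correlation); the call of HEY1 held in 5 of 16 alternatives. Of 19 tip-cell genes ESM1, PDGFB, ANGPT2 and CXCR4 fell; the median was 0.04 and the mean -0.24 (adjusted p = 0.393, and 0.0463 without COMP-Ang1 replicate 2). Of 27 endothelial junction genes GJA4, GJA5 and CGNL1, a tight junction adaptor, rose and OCLN, a tight junction protein, and CDH2, N-cadherin, fell (adjusted p = 0.362). Of 15 flow-responsive and vasoprotective genes NOS3, AQP1 and TEK rose and THBD and TXNRD1 fell (adjusted p = 0.101). Of 20 Tie2 pathway components TEK rose and 2 fell, ANGPT2 among them (adjusted p = 0.743). SLC2A3, a glucose transporter, rose in the glycolysis and hypoxia response list, whose median was 0.04 and mean 0.00 (adjusted p = 0.907). OAS2 rose in the type I interferon response list (adjusted p = 0.362), and THBS1 fell in the basement membrane and matrix list (adjusted p = 0.362). The calls of SLC2A3, OAS2, THBS1 and PLAU held in 7 of 17, 6 of 16, 5 of 17 and 6 of 17 alternatives.

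No member was called by limma in the lists of cholesterol synthesis (camera adjusted p = 0.438), MYC and ribosome biogenesis (0.393), cell cycle (0.991), ATF4 and amino acid response (0.736), apoptosis and survival (0.907), or heat shock and unfolded protein response (0.525). The ATF4 list had a median log2 change of 0.01 and a mean of -0.04, and the apoptosis list a median of -0.01 and a mean of 0.01. Of the markers of other cell types, the 7 tested smooth muscle, pericyte and fibroblast markers, the 1 leukocyte marker and the 5 lymphatic endothelial markers had 0 called by limma in this contrast, and KRT19 was the 1 called of 3 epithelial and keratinocyte markers. All 3, KRT8, KRT18 and KRT19, rose when adjusted over the list alone, with a median log2 change of 0.37 against 0.09 for endothelial identity. The other members of that list of 10 did not pass the filter. The most abundant were RGS5 at 354 FPKM, KRT18 at 308, NRP2 at 99.6 and CD68 at 40.5 as means over the 8 libraries. No erythroid or platelet marker passed the filter, and the highest was HBA1 at 0.104 FPKM.

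**Figure D2:**
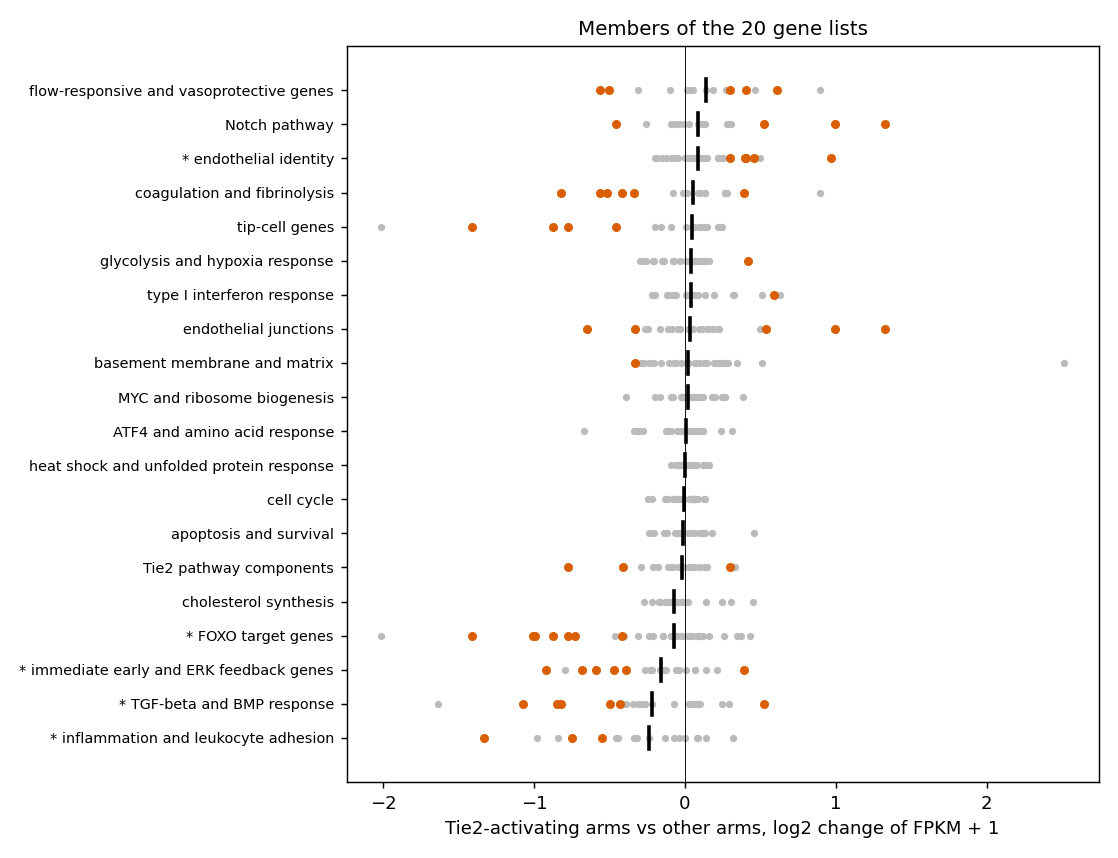
Log2 change of FPKM + 1 between the Tie2-activating arms and the other arms for each tested member of the 20 gene lists, with called members in orange, others in grey, a black bar at each list's median, and an asterisk on the 5 lists with a camera adjusted p under 0.05. NOTCH1 is not drawn as a point. The inflammation and leukocyte adhesion list has the lowest median, at -0.24.

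ABA with Ang2 was compared with control to ask what the blocking antibody with its ligand does by itself. Of the genes that changed in the activating arms, ESM1 had 35.8 ± 1.92 FPKM in control and 36.0 ± 3.57 with ABA (SD, n = 2; log2 change 0.01, limma adjusted p = 0.997), and GJA4 had 26.3 ± 4.37 and 25.7 ± 1.48. ANGPT2 and ICAM1 had log2 changes of 0.26 and 0.33, and neither passed the threshold (adjusted p = 0.958 for both). Only the loci listed as SNORA10, the symbol of a small nucleolar RNA, and LOC729234, a provisional symbol, were called by limma, and 554 genes had an unadjusted p under 0.05. LOC729234 had 4.99 ± 0.16 FPKM with ABA and 0.644 ± 0.0371 in control (log2 change 1.86, adjusted p = 0.0275), and the call held in 8 of 17 alternatives. SNORA10 was listed at 0 in every library except the ABA libraries, at 93.2 and 70.8 FPKM. Its listed locus spans 2012062 to 2014827 on chromosome 16 (hg19), and its fragments may belong to another gene in that span. A rise of this small RNA with ABA is therefore not shown. The count was 1 without control replicate 1 or either ABTAA library and was not above 3 without any other library. Of the lists, cell cycle (camera adjusted p = 7.01e-05) and MYC and ribosome biogenesis (adjusted p = 0.0202) were higher, with adjusted p = 0.524 and 0.483 with an estimated correlation, and 0 of their 33 and 32 members were called by limma. Camera called 6 lists in ABA against control without control replicate 1, 0 without control replicate 2 and 1 without either ABA library.

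COMP-Ang1 and ABA with Ang2 were also set against each other, groups that differ by the ligand, the antibody and Ang2. This contrast alone does not assign a change to any 1 of them. With COMP-Ang1, MCTP1 was lower than with ABA (log2 change -1.65, limma adjusted p = 0.000108), as were CXCL1 (-1.62, adjusted p = 0.00191), ESM1 (-1.54, adjusted p = 0.00283), ICAM1 (-0.99, adjusted p = 0.0132) and ANGPT2 (-0.93, adjusted p = 0.0201). CCL2 had 211 ± 22.2 FPKM with COMP-Ang1 and 478 ± 42.1 with ABA (SD, n = 2), a log2 change of -1.18 (limma adjusted p = 0.0107). F2R, F2RL1 and THBD were lower, with log2 changes of -0.51, -0.77 and -0.69. They were not among the genes repeated under the alternatives in this contrast. The coagulation and fibrinolysis list that holds them was not called, with a median of 0.06 and a mean of -0.04 (camera adjusted p = 0.892, and adjusted p = 0.938 with an estimated correlation). GJA4, SLCO2A1, AQP3, APCDD1 and TSPAN18, a tetraspanin, were higher, with log2 changes of 1.18, 1.25, 1.17, 1.04 and 0.86. This contrast gave 102 called genes, 30 higher and 72 lower, with 1800 at an unadjusted p under 0.05. Camera placed FOXO targets lower and endothelial identity higher (adjusted p = 0.00159 for both), and inflammation and immediate early genes (0.00447 for both) and TGF-beta and BMP response (0.00572) lower, with adjusted p between 0.33 and 0.553 with an estimated correlation. With NOTCH1 and EIF2C2 left out the Notch list was higher (adjusted p = 0.0187, and adjusted p = 0.425 with an estimated correlation). The 3 epithelial and keratinocyte markers tested rose when adjusted over the list alone, with a median log2 change of 0.48 against 0.09 for endothelial identity. The count was 12 without either ABA library, 14 and 22 without COMP-Ang1 replicates 1 and 2, and 53 and 52 without ABTAA replicates 1 and 2.

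The log2 changes by COMP-Ang1 against control and by ABTAA against ABA share no library and were set side by side. The calls of both came from the fit of all 8 libraries and share its estimate of the spread, so they are not independent. Fits of only the groups compared called 4 and 11 genes by limma, and the overlap of those calls was not counted. Of the 27 genes called after COMP-Ang1, without NOTCH1 and EIF2C2, 27 had a log2 change of the same sign between ABTAA and ABA and 20 were also called there. Among these 20 were the rising genes EPHB1, GJA4, LIPG, PLVAP and SLCO2A1 and the falling genes CTGF, CXCL1, ESM1 and MCTP1. Of the 53 genes called in either, 47 had the same sign in both (88.7%), against 63.7% of all genes tested. Across all 11823 genes, which are not independent replicates, r was 0.249 and rho 0.396, and r was 0.127 without COMP-Ang1 replicate 2, 0.141 without ABA replicate 2, 0.153 without ABTAA replicate 1 and 0.156 without control replicate 1.

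COMP-Ang1 and ABTAA were each also compared with the same controls, and 5 genes were called higher and 13 lower in both. Independent lists of these sizes would share 0.00254 and 0.0249 genes, and simulated unchanged groups against the same controls shared 0.15 on average and 2 at most. Across genes r was 0.542 and rho 0.609, where the simulation of unchanged groups gave r between 0.259 and 0.770 with a mean of 0.505. The covariance was 0.0362, a difference of 0.0144 from the simulated mean of 0.0217 and inside the simulated range of 0.0102 to 0.0574. The r and the covariance across genes thus lie within the range of this simulation, and rho was not simulated. The simulation drew independent noise for each gene and did not keep values at or above 0. Whether a few loci with a large spread set the width of its range was not tested. Since the simulated range was wide, a shared response across genes is neither shown nor excluded by these values. With 2 control libraries the controls could not be split, so part of the shared calls may come from them as well. Without COMP-Ang1 replicate 2 r was 0.345.

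**Figure D3:**
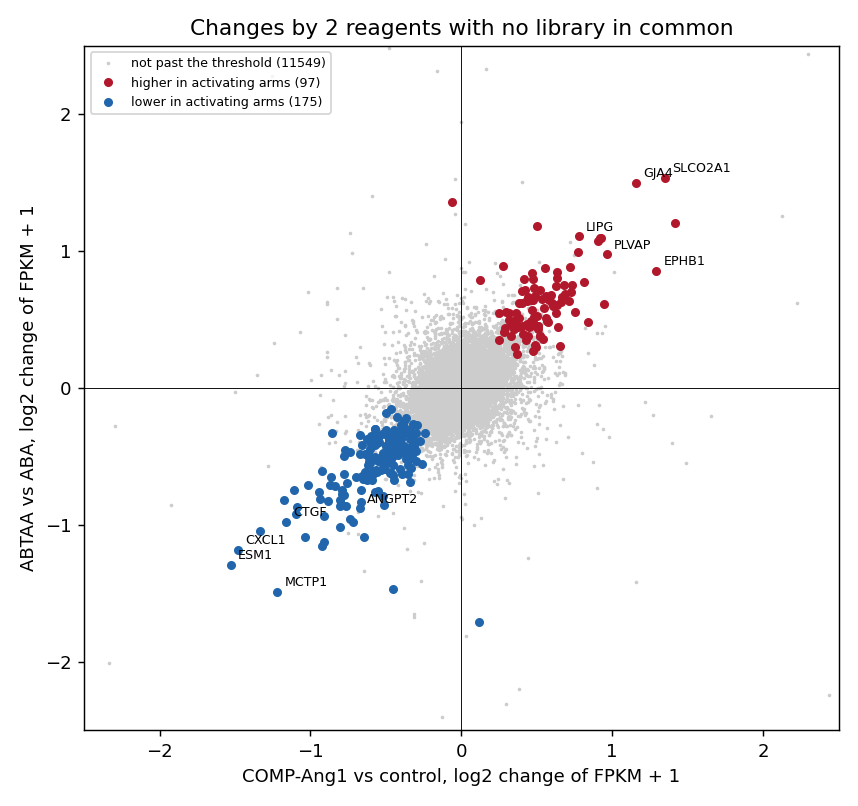
Log2 change of FPKM + 1 by COMP-Ang1 against control (horizontal axis) and by ABTAA against ABA (vertical axis), with 1 point per gene. Genes called higher in the Tie2-activating arms are red, those called lower are blue and the 11549 others are grey. NOTCH1 and EIF2C2 are not drawn, and 21 loci, 1 of them called, lie outside the axes. The calls were made on the mean of both axes, which favours genes with the same sign on both.

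ABTAA with Ang2 was compared directly with COMP-Ang1 to ask whether these groups differ, which they may do through the antibody, the ligand or Ang2. The difference was 0.25 log2 for ESM1 (95% interval -0.05 to 0.54), 0.16 for MCTP1 (-0.04 to 0.36), 0.13 for CTGF (-0.14 to 0.40), 0.06 for ANGPT2 (-0.24 to 0.35) and 0.32 for GJA4 (-0.03 to 0.67). CXCL1 was 0.44 higher with ABTAA (0.15 to 0.73) and PLVAP 0.42 higher (0.18 to 0.67), intervals not adjusted for the number of genes, and neither passed after adjustment (limma adjusted p = 0.997 for both). Over the 53 genes called in COMP-Ang1 or ABTAA against control or in ABTAA against ABA, 7 intervals excluded 0, a count with no chance level since the genes were chosen from the same libraries, and the median width to each side was 0.27. NOTCH1 and EIF2C2 were the 2 genes called by limma, with 469 at an unadjusted p under 0.05. Both were listed at 0 in the COMP-Ang1 libraries, and without them the count was 0. The count was 8 without COMP-Ang1 replicate 2, 6 and 3 without ABTAA replicates 2 and 1, and 4 without either control library. The FOXO list was higher and the MYC and interferon lists lower with ABTAA (camera adjusted p = 0.025 for each), with adjusted p = 0.486, 0.337 and 0.337 with an estimated correlation.

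The interaction asked whether ABTAA against ABA differs from COMP-Ang1 against control. ESM1 had an interaction of 0.24 log2, ANGPT2 of -0.21, ICAM1 of -0.17 and TEK of 0.10, and none of these passed (limma adjusted p = 1.00 for each). NOTCH1, EIF2C2 and SNORA10, each listed at 0 in whole groups, were the 3 genes called, with 378 at an unadjusted p under 0.05. Of the lists, camera placed MYC and ribosome biogenesis (adjusted p = 0.000107) and cell cycle (0.0159) lower in the interaction and Notch pathway (0.0159), flow-responsive genes (0.0264) and tip-cell genes (0.0264) higher, with adjusted p between 0.13 and 0.531 with an estimated correlation. With NOTCH1 and EIF2C2 left out the Notch list was not called (adjusted p = 0.183, and adjusted p = 0.615 with an estimated correlation). The count of genes was 9 without ABTAA replicate 2, 7 without COMP-Ang1 replicate 2 and 5 without ABA replicate 1. Any difference among the 4 groups was called for 64 genes (1277 at an unadjusted p under 0.05). That count was 24 and 25 without ABA replicates 1 and 2, 26 and 33 without COMP-Ang1 replicates 1 and 2, 32 and 35 without ABTAA replicates 1 and 2, and 39 and 34 without control replicates 1 and 2.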

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

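The interaction was planned, and the tests of explanations in this part were chosen after the results were seen, with the criterion for ABA made stricter after a first result. The interaction was called for NOTCH1 (fitted log2 difference 5.44), EIF2C2 (4.48) and SNORA10 (-6.36), because the change between ABTAA and ABA differed from that between COMP-Ang1 and control. These fitted values depend on the pseudocount, since each gene was listed at 0 in whole groups. SNORA10 was listed at 0 in all libraries but ABA, and no explanation was tested for it, including an assignment of fragments from another gene in its span.

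NOTCH1, a Notch receptor on chromosome 9, 139388896 to 139440266 (hg19), was listed at 34.9 and 46.0 FPKM in control, 0 and 0 after COMP-Ang1, 38.4 and 42.5 with ABA, and 41.5 and 44.1 with ABTAA. EIF2C2, which encodes the Argonaute protein AGO2, on chromosome 8, 141530266 to 141645658, was listed at 23.5 and 28.1, 0 and 0, 25.1 and 32.7, and 19.9 and 28.6 FPKM. Failed estimates are a candidate explanation: 18 other loci were listed at 0 in a single library while at 10 FPKM or more in the other 7, and 4 loci in 2 libraries of different groups, 3 of them in libraries that share neither Ang2 nor Tie2 activation. Such zeros thus also arise without a shared treatment, but NOTCH1 and EIF2C2 are the 2 loci listed at 0 in both libraries of 1 group and at 10 FPKM or more in the 6 others. A real loss of these transcripts after COMP-Ang1 stays open, because 0 occurred in both libraries of that group and no reads were analysed here.

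The 274 genes called between the activating arms and the other arms were the largest count among the 8 contrasts. In a 2-group fit the real split of the 8 libraries gave 386 genes. It was 1 of 35 splits with so many, the lowest share possible. The highest of the others gave 3, which is not a chance level. Those splits mix the arms, so an arm difference adds to their spread and lowers their counts. Chance can be excluded only if the 8 libraries are independent samples, which the labels do not show. A different scale of the libraries is argued against as the whole cause, since 254 of the 274 genes were also called after median-of-ratios scaling. If 1 reagent alone drove the averaged contrast, the interaction, which is orthogonal to it, would be 2 times the averaged change, with the opposite sign for COMP-Ang1 alone and the same sign for ABTAA alone, a ratio of -1 or 1. The median ratio was 0.0123 (SD 0.203) over 272 called genes, leaving out NOTCH1 and EIF2C2, which argues against either reagent alone. A shared response to Tie2 activation is therefore a hypothesis that these data leave standing, but any difference in handling that follows the same arms was not tested.

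The genes called in the activating arms were read in ABA against control, a contrast orthogonal to the one that picked them. Of the 175 genes lower in the activating arms, 111 were higher with ABA than in control, with a median log2 change of 0.06 (camera p = 9.31e-05, and p = 0.153 with an estimated correlation). Of the 97 higher ones 32 were higher with ABA, with a median of -0.08 (camera p = 0.00101, and p = 0.138 with an estimated correlation). Whether ABA with Ang2 moves these genes the opposite way cannot be told apart from correlated variation between libraries. ABA and Ang2 were given together, so neither could be weighed alone.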

How the results depend on the processing

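Removing NOTCH1 and EIF2C2, the loci listed at 0 in both libraries of 1 group and at 10 FPKM or more in the others, and leaving NOTCH1 out of its list were tests chosen after the data were seen; the other alternatives were fixed before. Of 135 called results for named genes, 40 were called under every alternative that gave them a value and 0 reversed; 9 of the 40 belong to NOTCH1 and EIF2C2, which have no value where they are removed; 619 of 2346 repeats kept the direction but missed the threshold. Apart from these 2 genes, 26 results were called throughout in the arms, 1 in COMP-Ang1 against control, 1 in ABTAA against ABA, 3 in COMP-Ang1 against ABA and 0 in ABTAA against control (limma; 988 at an unadjusted p under 0.05). Depth in fragments was unknown, so its limit on low genes could not be given.

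Counts of called genes moved by more than 1.5 times as follows, and the cause was not tested unless stated. Without the filter, which adds lowly expressed loci to the tests, the counts were 12 (COMP-Ang1 against control), 9 (ABTAA against control), 1 (ABA against control), 3 (ABTAA against ABA), 17 (COMP-Ang1 against ABA), 165 (arms) and 17 (any difference). A filter of 5 FPKM gave 47, 31 and 1 for the 3 contrasts with control. Robust eBayes gave 48 for COMP-Ang1 and 47 for ABTAA against control, and 72 for ABTAA against ABA. Median-of-ratios scaling gave 32 for ABTAA against control, and a pseudocount of 0.1 gave 1 for ABA against control. Fitting only the groups compared, which leaves fewer samples for the spread, gave 4 for COMP-Ang1 and 0 for ABTAA against control (limma; 19 in the fit of all groups, 988 there at an unadjusted p under 0.05), 11 for ABTAA against ABA, 7 for ABTAA against COMP-Ang1 and 45 for COMP-Ang1 against ABA. Refitting without NOTCH1 and EIF2C2 gave 0 for ABTAA against COMP-Ang1 (limma; 469 at an unadjusted p under 0.05 with them) and 1 for the interaction, SNORA10, since these 2 loci were the other calls.

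The replicate numbers were not shown to pair the libraries: correlations of the deviations of same-numbered libraries were 0.26, -0.08, 0.05, -0.21, -0.12 and -0.06. With the replicate number as a block, the counts were 1 for ABA against control, 52 for COMP-Ang1 against ABA and 38 for any difference; the other counts stayed within 1.5 times.

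Leaving out 1 library at a time, which leaves fewer samples and assumes the lone sample of a group to vary like the other groups, gave 3 to 19 genes for COMP-Ang1 against control, 1 to 17 for ABTAA against control, 1 to 3 for ABA against control, 3 to 28 for ABTAA against ABA, 2 to 8 for ABTAA against COMP-Ang1, 12 to 75 for COMP-Ang1 against ABA, 88 to 180 for the arms, 3 to 9 for the interaction and 24 to 39 for any difference. Called lists numbered 3 to 9, 3 to 7, 0 to 6, 0 to 5, 3 to 6 and 1 to 6 for COMP-Ang1, ABTAA and ABA against control, ABTAA against COMP-Ang1, COMP-Ang1 against ABA and the interaction. In the arms, the adjusted p lay between 0.00162 and 0.057 for FOXO targets, 0.0463 and 0.92 for tip-cell genes, and 0.00021 and 0.0556 for TGF-beta and BMP response. The correlation across genes lay between 0.127 and 0.274 for COMP-Ang1 against control with ABTAA against ABA, and between 0.345 and 0.699 with ABTAA against control.

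Camera called 7, 5, 2, 7, 3, 5, 5 and 5 lists in the 8 contrasts, and 0 in each with an estimated correlation. By fry the counts were 4 for COMP-Ang1 against control, 6 for COMP-Ang1 against ABA and 8 for the arms. They were 0 for ABTAA and ABA against control, ABTAA against ABA, ABTAA against COMP-Ang1 and the interaction. In the arms, the adjusted p with an estimated correlation was 0.409 for FOXO targets, inflammation, and TGF-beta and BMP response, 0.431 for endothelial identity and 0.457 for immediate early genes. By fry, Tie2 components and interferon response had an adjusted p of 0.0451 and coagulation 0.0122. The Notch list had 0.0287 without NOTCH1, against 0.322 with it.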

Other observations

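All tests in this part were chosen after the results were seen, and their lists were made from general knowledge after the called genes were known. Targets of the transcriptional co-activator YAP and its partner TEAD include CTGF, CYR61 and ANKRD1, which fell in the activating arms with log2 changes of -1.07, -0.43 and -1.06 (limma adjusted p = 0.000816, 0.0292 and 0.000262). The symbol ANKRD1 is found on more than 1 locus. Of 19 targets tested 6 fell and 0 rose (camera p = 3.07e-05, and p = 0.0608 with an estimated correlation). A general fall of YAP and TEAD targets may be behind this. The 14 targets in no earlier list and not among the named genes, without ANKRD1, had a median log2 change of -0.11, with CRIM1 and RBMS3 falling. They were lower by camera (p = 0.0296), but p was 0.288 with an estimated correlation. CRIM1 and RBMS3 were already among the called genes when the list was made. This part of the list therefore gives no independent support, and the hypothesis stays open. ANKRD1 was taken out of this part, and the estimated correlation was made part of the criterion here and for arterial genes, only after a first result was seen.

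Rises of GJA4, GJA5 and HEY1, with log2 changes of 1.33, 0.99 and 0.53, might belong to a wider rise of arterial genes. Of 19 arterial genes tested, these 3 rose, CXCR4 and ALDH1A1 fell, and the median log2 change was -0.01 while the mean was 0.10 (camera p = 0.283, and p = 0.476 with an estimated correlation). The 7 arterial genes in no earlier list and not among the named genes had a median of -0.09 (camera p = 0.0715, towards lower, and p = 0.137 with an estimated correlation). This shows no wider rise and, with so few genes, does not exclude one. ALDH1A1, 1 of these 7, was already a called gene when the list was made. Of 9 venous genes 0 were called by limma, NRP2 among them, with a median log2 change of 0.09 (camera p = 0.0561, and p = 0.118 with an estimated correlation).

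Loci without a gene symbol were tested apart. Of 3244 that passed the filter, 0 were called by limma in any of the 8 contrasts, and 268 had an unadjusted p under 0.05 in the activating arms where 162 were expected by chance.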
